A study of Mus musculus with 6 samples.

How the data were processed

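RNA was measured in gastrocnemius of male C57BL/6 mice after 12 weeks on a normal or a high phosphate diet, 3 libraries for each diet. Total RNA was extracted with TRIzol and sequenced on Illumina instruments, per the labels' protocols. The deposited counts are whole-number counts per Ensembl gene, not normalized, and the authors also deposited FPKM values for the same libraries. Per the submitters' processing notes, which give no roles or order, the tools were Trim Galore 0.4.1, HISAT2 2.0.1, featureCounts 1.4.6 and DESeq2 1.6.3, with the GRCm38 build. The annotation release, the strand setting of the counting and the tool behind the FPKM values are not given in the sources used here. Without a strand setting, reads from overlapping genes on opposite strands cannot be told apart. The count table holds 47967 genes, and 38011 have FPKM values. All 37 mitochondrially encoded genes had a count of 0 in every library, so the mitochondrial share could not be used as a sign of RNA quality. Among 9870 genes with at least 100 counts in every library, the ratio of FPKM to CPM differed by over 1.2-fold between libraries in 43.2%, so the deposited FPKM values are not these counts divided by a fixed gene length. Fold changes from counts and from FPKM correlated at 0.75 across genes, which are not independent replicates.

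Libraries were assigned to diets and numbered from the sample labels. No library was left out. The libraries held 21856006 to 27474251 gene counts, so a gene at 1 CPM had 21.9 counts in the smallest, a counting error of 21.4%, and the median SE of a log2 fold change was 0.16. Libraries of one diet correlated at 0.981 to 0.989 across genes, and their counts differed by 18.3 to 60.4 times the sampling noise (chi-square per degree of freedom), so no library was a copy of another. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the counts, with TMM normalization, the filterByExpr filter, robust estimation and Benjamini-Hochberg adjustment over 15347 genes. A gene was called at an adjusted p under 0.05 with no limit on the fold change. The common biological coefficient of variation was 0.161. TMM factors were 1.18 ± 0.0955 on the normal and 0.849 ± 0.0473 on the high phosphate diet. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate.

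Before the data were examined, 23 function lists and 12 cell type marker lists were fixed, together with the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation between genes of 0.01 and with adjustment within each kind of list. This covered 22 function lists and 11 cell type lists. Camera with an estimated correlation and fry were run beside it. Members called over all genes and members called when adjusted over the list alone were both counted. Named were the 10 genes with the largest change in each direction among those called, with a mean of at least 1 CPM and no overlap between the diets, leaving out predicted genes and pseudogenes. To these were added up to 5 called members by smallest p from each of 4 fatty acid lists, up to 3 from every other list, and 17 genes fixed in advance, giving 135 genes. A further 29 genes were named after their values were seen, because they stood among 5 or fewer called members of a list in their direction. Marker scores per library were the mean log2 CPM of a list, compared by a two-sided exact permutation test.

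The alternatives were size factors in the style of DESeq2, library size alone, TMM without the 50 most abundant genes, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, the white adipocyte score as a covariate, leaving out each library in turn, DESeq2 1.42.0, limma-voom, and limma with a trend on the FPKM values with pseudocounts of 1 and 0.1. Other thresholds were an adjusted p under 0.1 and a change of at least 2-fold. A run without cell type markers and immunoglobulin genes was added after the data were seen. Tested on simulated data with 200 changed genes among 15091, drawn with the means, dispersions and library sizes of the high against normal phosphate comparison, the edgeR fit recovered 20.9% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 90.9% of those changed 4-fold. Of its 130 calls there, 15 (11.5%) were false, above the nominal 5%. As many simulated genes were raised as lowered, and they were few, whereas 49.3% of the genes tested were called in the real comparison. The recovered and false shares therefore need not hold for the real data, and this simulation does not test the normalization. In a second simulation of the same comparison, over 15347 genes, camera with the preset correlation called the shifted list and 0 of 30 unshifted lists. Its genes were drawn independently of each other and its lists at random, so it cannot vouch for the preset correlation. Estimated correlations of the real lists reached 0.90, for oxidative phosphorylation. Coordinates are from GENCODE release M21 on GRCm38, in which 47601 of the 47967 gene identifiers (99.24%) were found, all 164 named genes among them. Exon overlap between genes and transcript stretches of 50 bases shared with other genes were computed from the same release, also for the called members of the lists added later.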

Results

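Gene expression was measured by RNA sequencing in gastrocnemius, the large calf muscle, of male C57BL/6 mice. The mice were 20 to 24 weeks old. They ate either a normal phosphate diet (0.6% inorganic and 0.9% total phosphate) or a high phosphate diet (2.0% inorganic and 2.3% total phosphate) for 12 weeks, and the diets were matched for sodium (0.9%), potassium (1.8%), calcium (1.9%) and magnesium (0.3%). There were 3 libraries per diet. The normal phosphate libraries held 23722802, 21968552 and 23670055 gene counts (replicates 1, 2 and 3), and the high phosphate libraries 27474251, 22560360 and 21856006. The labels do not state that each library came from a separate mouse, so all p-values measure only the spread between these samples, which may be technical. Levels are given in TMM-normalized CPM as mean ± SD with n = 3 libraries per diet. Log2 fold changes are high over normal phosphate, ± SE, and positive values mean higher on the high phosphate diet.

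The comparison between the diets addressed how a high phosphate intake alters the muscle transcriptome, with fatty acid metabolism as the subject named in the series title. Genes of fatty acid synthesis, white adipocytes, connective tissue and immune cells were lower on the high phosphate diet. Genes of fast fibres, glycogen and glucose use, fatty acid oxidation and muscle atrophy were higher. These are calls of camera at a preset correlation, and with an estimated correlation none was kept (camera adjusted p = 0.565 or more). With library size alone 4 fatty acid oxidation genes rose and 2 fell. Fasn, the fatty acid synthase, fell from 530 ± 112 to 66.0 ± 18.4 CPM, a log2 fold change of -3.01 ± 0.25. Fbxo32, a ubiquitin ligase of muscle atrophy, rose from 176 ± 62.7 to 942 ± 453 CPM, a log2 fold change of 2.42 ± 0.39.

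Of 15347 genes tested, 7563 (49.3%) changed between the diets by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 3528 rose and 4035 fell. At a change of at least 2-fold, 686 rose and 2076 fell. The 3 libraries of one diet all lay on the same side of the 3 of the other in 9578 of the genes tested (62.4%), 7461 of them called, where chance gives 10%. The first principal component held 77.3% of the variance. The high phosphate libraries sat at 53.0, 51.1 and 51.5 on it, and the normal phosphate libraries at -36.5, -75.4 and -43.8, with replicate 2 apart from the rest of its diet. The 10 most abundant genes took 14.9 ± 1.65% of the counts on the normal phosphate diet and 22.5 ± 1.34% on the high phosphate diet. Myh4, the myosin heavy chain of the fastest fibres, alone took 1.97 ± 0.341% and 4.48 ± 0.984%. Scaling by library size alone, which leaves this difference in place, moved the median log2 fold change of all genes from -0.016 to -0.49 and the split to 878 genes higher and 7886 lower. The authors' FPKM values, tested with limma as log2(FPKM + 1), gave 718 higher and 5655 lower, with a median of -0.29. The directions below are therefore relative to a typical gene.

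**Figure D1:**
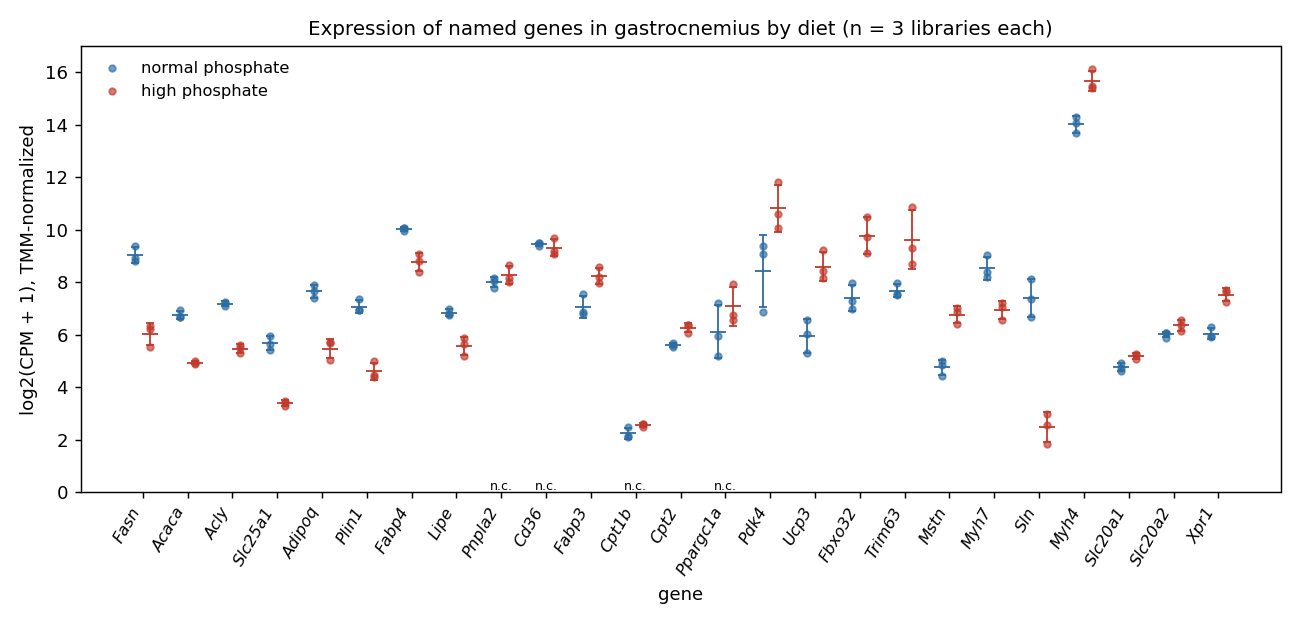
TMM-normalized expression of 25 genes, on a log2(CPM + 1) scale (vertical axis), in the normal (blue) and high (red) phosphate libraries; dots are the 3 libraries of a diet, and the horizontal marks and bars are their mean and SD. The 4 genes marked n.c. did not pass the test, and in the 21 others the diets do not overlap. Slc20a1 and Slc20a2 are higher here but turn to -0.023 and -0.11 with library size alone.

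The largest increases among genes whose diets did not overlap were in Odf3l2, BC048679, Slc15a5, Rasd2, Dach2, Slc4a10, Neto2, Tmem132b, Arrdc2 and Chac1, all rising by 3.08 to 5.17 on the log2 scale. Odf3l2 rose from 2.10 ± 0.241 to 75.4 ± 27.5 CPM (edgeR adjusted p = 0.000121). Slc15a5, a member of a family of peptide transporters, rose from 1.39 ± 0.204 to 25.4 ± 3.58 CPM (edgeR adjusted p = 1.55e-05). Rasd2, a small GTPase, rose from 7.67 ± 2.88 to 126 ± 12.3 CPM, and Arrdc2 from 21.3 ± 6.99 to 185 ± 76.6 CPM. Neto2 (3.46 ± 0.16), Tmem132b (3.36 ± 0.37), Dach2 (3.71 ± 0.56) and Slc4a10 (3.52 ± 0.45) rose from a low level of 0.380 to 2.39 CPM, and BC048679 (4.49 ± 0.33) from 0.255 CPM. On the log2(FPKM + 1) scale, which shrinks the changes of low genes, Slc4a10 (0.29) and Tmem132b (0.34) were not called. Chac1, which degrades glutathione, rose from 15.1 ± 3.43 to 128 ± 50.4 CPM.

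The largest decreases among genes whose diets did not overlap were in Ighg2b, Igkv19-93, Igkv14-111, Pax5, Ly6d, Ms4a1, Cthrc1, Cr2, Fbn2 and Sln. Ighg2b, an immunoglobulin heavy chain, fell from 28.3 ± 12.5 to 0.136 ± 0.111 CPM, a log2 fold change of -7.69 ± 0.53 (edgeR adjusted p = 0.000182). Cr2 (-6.44 ± 1.43), Ms4a1, which encodes CD20 (-5.76 ± 1.18), the transcription factor Pax5 (-5.25 ± 0.97) and Ly6d (-5.23 ± 0.99) fell as well. Without normal phosphate replicate 2, Cr2 lost its call (log2 fold change -6.05, edgeR adjusted p = 0.0532). Cr2 (-0.98) and Pax5 (-0.41) were not called on the log2(FPKM + 1) scale. Calls were also lost with limma-voom for Pax5 (-4.83), Ms4a1 (-5.79), Cr2 (-5.80) and Fbn2 (-4.10), at limma-voom adjusted p values of 0.0534, 0.0754, 0.0697 and 0.0957, and with no filter on low counts for Cthrc1 (-4.97), Cr2 (-6.42) and Fbn2 (-5.03), at edgeR adjusted p values of 0.0547, 0.0615 and 0.127. Normal phosphate replicate 1 had 1.11 CPM of Pax5, against 8.47 and 8.02 in replicates 2 and 3. The light chain segments Igkv14-111 and Igkv19-93 had only 3 counts each over the high phosphate libraries, so their fall is given as a ratio of normal to high phosphate. It was 96.4 for Igkv14-111 (95% counting interval 32.8 to 470) and 40.2 for Igkv19-93 (13.5 to 197). The more abundant heavy chain Ighm, named here after its value was seen, rose from 213 ± 9.62 to 350 ± 91.3 CPM (0.72, edgeR adjusted p = 0.0118), a call lost with library size alone (0.23) and on the log2(FPKM + 1) scale (0.12). Of the 50-base stretches of Ighg2b 4.15% occur in transcripts of other genes, and of those of Ighm, Igkv14-111 and Igkv19-93 0%. Sln, which encodes sarcolipin, a regulator of the sarcoplasmic calcium pump, fell from 182 ± 91.4 to 4.82 ± 2.16 CPM (-5.24 ± 0.53, edgeR adjusted p = 0.000814). The collagen-processing gene Cthrc1 (-4.99 ± 1.07) and the fibrillin Fbn2 (-5.06 ± 1.5) were high mainly in normal phosphate replicate 2, at 20.4 and 11.6 CPM, and without that library Cthrc1 stood at -3.55 and Fbn2 at -2.87. Fbn2 lost its call on the log2(FPKM + 1) scale (-0.41) and without any of the high phosphate replicates, with edgeR adjusted p values of 0.0760, 0.0979 and 0.0979 without replicates 1, 2 and 3, at log2 fold changes of -5.77, -4.90 and -4.70.

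Genes of fatty acid synthesis fell as a group. Of its 16 measured members, 3 rose and 11 fell, and 14 changed when adjusted over the list alone, with a median log2 fold change of -1.15 (camera adjusted p = 0.00202, and adjusted p = 0.566 with an estimated correlation). Acaca, the acetyl-CoA carboxylase that supplies malonyl-CoA for synthesis, fell from 108 ± 11.7 to 29.6 ± 1.41 CPM (-1.87 ± 0.11, edgeR adjusted p = 5.84e-05). The citrate carrier Slc25a1 (-2.41 ± 0.16), Acly, which splits citrate in the cytosol (-1.73 ± 0.12), the elongase Elovl6 (-2.10 ± 0.17) and Fasn (-3.01 ± 0.25, edgeR adjusted p = 0.000184) fell as well. The white adipocyte marker score differed by -1.93 (95% interval -2.53 to -1.34) on the log2 scale in the same libraries. About 30.4% of the 50-base stretches of Acaca transcripts also occur in transcripts of other genes, among them Gm5182, so its count is uncertain to that extent.

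Genes of mitochondrial fatty acid oxidation were higher relative to other genes. Of its 26 measured members, 15 rose and 0 fell, and 16 changed when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 7.44e-05, and adjusted p = 0.566 with an estimated correlation). With library size alone 4 members rose and 2 fell, at a median of 0.024. The members with the smallest p were Acad11 (0.81 ± 0.12), Cpt2, the inner-membrane carnitine palmitoyltransferase (0.67 ± 0.11), the carnitine carrier Slc25a20 (0.77 ± 0.14), Mlycd, which breaks down malonyl-CoA (1.04 ± 0.19), and Etfdh (0.78 ± 0.15). Their edgeR adjusted p values ran from 0.00117 to 0.00268, and their levels on the normal phosphate diet from 38.4 to 132 CPM. Cpt2 (0.20) and Slc25a20 (0.30) were not called with library size alone, Acad11 (0.31), Cpt2 (0.20), Slc25a20 (0.31) and Etfdh (0.36) were not on the log2(FPKM + 1) scale, and the white adipocyte score given above was lower in the libraries in which these genes were higher. Cpt1b, the muscle isoform of the outer-membrane enzyme, was not called, at 3.74 ± 0.677 and 4.90 ± 0.244 CPM (0.39 ± 0.19, edgeR adjusted p = 0.111), although it was called without normal phosphate replicate 1 (0.55, edgeR adjusted p = 0.0447). It was also called as higher on the log2(FPKM + 1) scale (0.46, limma adjusted p = 0.0250), with a pseudocount of 0.1 (0.47, 0.0227) and over all genes above 0 in FPKM (0.46, 0.0479), whereas its sign turned with library size alone (-0.075). Of the exonic bases of Cpt1b, 81.4% are also annotated to Gm44502 on the same strand, so its count is uncertain.

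Genes of fatty acid uptake and activation moved both ways. Of its 17 measured members, 5 rose and 4 fell, and 9 changed when adjusted over the list alone. The list was not called (camera adjusted p = 0.478), and its median of 0.18 turned to -0.30 with library size alone and to -0.25 on the log2(FPKM + 1) scale, and to -0.042 without high phosphate replicate 2. Vldlr, a lipoprotein receptor, rose from 225 ± 29.0 to 655 ± 32.6 CPM (1.54 ± 0.16), and Fabp3, the heart and muscle fatty acid binding protein, from 136 ± 42.5 to 307 ± 68.6 CPM (1.17 ± 0.24, edgeR adjusted p = 0.00431). Acsl3, an acyl-CoA synthetase, rose (0.84 ± 0.14; not called with library size alone, 0.36, or on the log2(FPKM + 1) scale, 0.30), whereas its relative Acsl5 (-1.03 ± 0.12), Fabp5 (-1.54 ± 0.25) and the acyl-CoA binding protein Dbi (-0.71 ± 0.14) fell. The fatty acid translocase Cd36 was at 697 ± 30.8 and 647 ± 155 CPM and was not called (-0.11 ± 0.19, edgeR adjusted p = 0.664), and its sign turned without high phosphate replicate 1 (0.028), but it was called as lower with library size alone (-0.58, edgeR adjusted p = 0.0285) and on the log2(FPKM + 0.1) scale (-0.57, limma adjusted p = 0.0499). Fabp3 shares 37.3% of its 50-base stretches with other transcripts, mainly its pseudogene Fabp3-ps1.

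Genes of lipolysis and triglyceride storage also moved both ways. Of its 22 measured members, 8 rose and 7 fell, and 18 changed when adjusted over the list alone, and the list was not called (camera adjusted p = 0.894). Its mean was -0.17, and its median of 0.10 turned to -0.38 with library size alone and to -0.30 on the log2(FPKM + 1) scale, and to -0.038 without high phosphate replicate 2. Pck1 (-2.00 ± 0.20), G0s2, an inhibitor of adipose triglyceride lipase (-1.92 ± 0.19), the acyltransferases Agpat2 (-2.14 ± 0.26) and Dgat1 (-0.92 ± 0.13), and Lipe, the hormone-sensitive lipase (-1.26 ± 0.17, edgeR adjusted p = 0.000778), fell. Lipe went from 113 ± 10.6 to 47.4 ± 10.9 CPM. Pnpla2, the adipose triglyceride lipase, was at 255 ± 32.1 and 312 ± 75.8 CPM and was not called (0.29 ± 0.19, edgeR adjusted p = 0.229), with the opposite sign under library size alone (-0.17) and on the log2(FPKM + 1) scale (-0.20). The adipocyte genes Adipoq (-2.19 ± 0.21, 201 ± 33.7 to 44.3 ± 10.9 CPM, edgeR adjusted p = 0.000284) and Fabp4 (-1.23 ± 0.20, 1034 ± 50.04 to 440 ± 98.6 CPM) fell in the same libraries.

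Genes of phosphate transport and sensing showed no common direction. Of its 18 measured members, 7 rose and 6 fell, and 15 changed when adjusted over the list alone, with a mean of -0.19 and camera adjusted p = 0.687. The median of 0.26 turned to -0.21 with library size alone and to -0.22 on the log2(FPKM + 1) scale. Xpr1, the phosphate exporter, rose from 65.3 ± 9.76 to 185 ± 29.0 CPM (1.5 ± 0.16, edgeR adjusted p = 0.000372). The phosphate importers Slc20a1 (26.1 ± 2.82 to 35.6 ± 2.75 CPM, 0.45 ± 0.11, edgeR adjusted p = 0.0101) and Slc20a2 (63.5 ± 4.73 to 81.7 ± 11.6 CPM, 0.36 ± 0.13, edgeR adjusted p = 0.0369) rose relative to other genes, but both turned negative with library size alone (-0.023 and -0.11), and on the log2(FPKM + 1) scale neither was called (0.079 and -0.32). Slc20a2 lost its call without any of the libraries except high phosphate replicate 3, at log2 fold changes of 0.40, 0.30 and 0.39 without normal phosphate replicates 1, 2 and 3 and 0.38 and 0.27 without high phosphate replicates 1 and 2. Klb, the co-receptor beta-Klotho (-2.99 ± 0.29), and Slc37a2, a sugar-phosphate exchanger (-2.30 ± 0.30), fell. The white adipocyte (-1.93) and macrophage (-1.36) scores were lower in the libraries in which these genes were lower.

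Fibre genes divided by type. Slow fibre genes fell: 0 rose and 8 fell of 14 measured, 10 changed when adjusted over the list alone, and the median was -0.94 (camera adjusted p = 0.00402, and adjusted p = 0.592 with an estimated correlation). The slow troponins Tnnc1 (-1.61 ± 0.20), Tnni1 (-1.66 ± 0.21) and Tnnt1 (-1.49 ± 0.21) and the slow myosin heavy chain Myh7 (382 ± 121 to 124 ± 27.9 CPM, -1.62 ± 0.25, edgeR adjusted p = 0.00140) fell. Fast fibre genes rose: 12 rose and 0 fell of 16, 12 changed when adjusted over the list alone, and the median was 0.92 (camera adjusted p = 2.02e-05, and adjusted p = 0.566 with an estimated correlation). Mybpc2, the fast myosin-binding protein (1.84 ± 0.23), the fast-fibre actinin Actn3 (1.42 ± 0.25) and Myh4 (16866 ± 3652 to 53360 ± 15030 CPM, 1.66 ± 0.31, edgeR adjusted p = 0.00252) rose. Counts of Myh4 and Myh7 are uncertain, since 18.9% and 20% of their 50-base stretches occur in transcripts of other genes, chiefly other myosins. Genes of calcium handling and excitation-contraction coupling rose, 20 of 24, with 2 falling and 24 changed when adjusted over the list alone (median 0.86; camera adjusted p = 1.53e-05, and adjusted p = 0.566 with an estimated correlation). The sodium channel Scn4a (1.33 ± 0.20) and Stac3, a part of the coupling machinery (1.0 ± 0.15), rose, and Sln (-5.24) fell. The white adipocyte, fibroblast and macrophage scores were lower in the libraries in which the fast fibre genes were higher, as given beside the lists of these cells.

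Genes of glucose use rose with them. In the list of glycolysis, glycogen and glucose uptake, 23 rose and 3 fell of 30, 27 changed when adjusted over the list alone, and the median was 0.91 (camera adjusted p = 1.53e-05, and adjusted p = 0.566 with an estimated correlation). Ppp1r3c, which targets a phosphatase to glycogen, rose from 210 ± 33.3 to 976 ± 313 CPM (2.22 ± 0.25). The phosphorylase kinase subunit Phka1 (1.61 ± 0.22) and glycogenin Gyg (1.2 ± 0.18) rose too. Of the citric acid cycle and pyruvate oxidation genes, 12 rose and 0 fell of 24 and 12 changed when adjusted over the list alone (median 0.50; camera adjusted p = 0.000133, and adjusted p = 0.608 with an estimated correlation), but with library size alone 0 rose and 1 fell, at a median of 0.029. Pdk2 (0.79 ± 0.19), Pdhx (0.64 ± 0.14) and Pdk1 (0.54 ± 0.12) had the smallest p in that list, and all lost their call with library size alone (0.33, 0.17 and 0.065) and on the log2(FPKM + 1) scale (0.36, 0.17 and 0.060). Like Pdk4 below, Pdk2 and Pdk1 are kinases that restrain pyruvate oxidation, so the number of members that rose does not measure that oxidation. Nuclear-encoded subunits of oxidative phosphorylation shifted by less: 6 rose and 0 fell of 75, 0 changed when adjusted over the list alone, and the median of 0.28 (camera adjusted p = 0.000302, and adjusted p = 0.730 with an estimated correlation) turned to -0.18 with library size alone and to -0.18 on the log2(FPKM + 1) scale. With library size alone 0 rose and 18 fell, and the list was not called (camera adjusted p = 0.0616), nor was it on the log2(FPKM + 1) scale (0.362). Ndufa12 (0.64 ± 0.17), Ndufs3 (0.59 ± 0.17) and Ndufa10 (0.51 ± 0.17) were its members with the smallest p, and none was called with library size alone (0.18, 0.12 and 0.050) or on the log2(FPKM + 1) scale (0.23, 0.19 and 0.23). Ndufs3 lost its call without high phosphate replicate 1 (0.55) or 2 (0.58), and Ndufa10 without those (0.51 and 0.48) or normal phosphate replicate 3 (0.49). In the same libraries the white adipocyte (-1.93), macrophage (-1.36) and fibroblast (-0.83) scores were lower. All 13 mitochondrially encoded subunits had a count of 0 in every library and could not be tested.

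Regulators and targets of PPAR and PGC-1, which control fatty acid use and mitochondrial content, rose. Of its 20 measured members, 11 rose and 0 fell, and 13 changed when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.00202, and adjusted p = 0.566 with an estimated correlation). Ucp3, a mitochondrial carrier of muscle, rose from 65.1 ± 27.6 to 405 ± 162 CPM (2.64 ± 0.39), Rxrg from 42.0 ± 12.7 to 111 ± 6.14 CPM (1.4 ± 0.21) and Esrrb from 3.02 ± 0.651 to 8.90 ± 2.18 CPM (1.56 ± 0.24). Pdk4, the kinase that shuts off pyruvate oxidation in fasted muscle, rose from 438 ± 285 to 2053 ± 1327 CPM (2.23 ± 0.73, edgeR adjusted p = 0.0420), with a spread that made this call fragile. It was lost without normal phosphate replicate 1 (2.65, edgeR adjusted p = 0.0532) or 2 (2.40, 0.172), and without high phosphate replicate 2 (1.58, 0.0997) or 3 (2.41, 0.0641). It was lost too with library size alone (1.77), with no filter on low counts (2.24) and on the log2(FPKM + 1) scale (1.89). Beside the rise of these genes the white adipocyte (-1.93), macrophage (-1.36) and fibroblast (-0.83) scores were lower. Ppargc1a, which encodes PGC-1 alpha, was at 80.6 ± 57.3 and 148 ± 82.5 CPM and was not called (0.88 ± 0.62, edgeR adjusted p = 0.279), but was without normal phosphate replicate 1 (1.62, edgeR adjusted p = 0.0463), while it stood at 0.52 without normal phosphate replicate 2 and 0.33 without high phosphate replicate 2.

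Genes of muscle atrophy and autophagy rose. Of its 28 measured members, 16 rose and 2 fell, and 19 changed when adjusted over the list alone, with a median of 0.73 (camera adjusted p = 0.000313, and adjusted p = 0.566 with an estimated correlation). Fbxo32 rose (2.42 ± 0.39, edgeR adjusted p = 0.00198), as did Mstn, which encodes the growth inhibitor myostatin (26.3 ± 5.29 to 110 ± 23.9 CPM, 2.06 ± 0.20), Trim54 (1.52 ± 0.18) and the autophagy kinase Ulk1 (1.16 ± 0.14). Trim63, the other classical ubiquitin ligase of atrophy, rose from 205 ± 38.1 to 964 ± 780 CPM (2.23 ± 0.55, edgeR adjusted p = 0.0130), and lost its call without normal phosphate replicate 2 (2.16, edgeR adjusted p = 0.122) or 3 (2.15, 0.0589), and without high phosphate replicate 2 it stood at 1.35. Its call was lost too with no filter on low counts (2.24) and on the log2(FPKM + 1) scale (1.47). As with the fast fibre genes, the white adipocyte (-1.93), macrophage (-1.36) and fibroblast (-0.83) scores were lower in the libraries in which atrophy genes were higher. Of the exonic bases of Trim54, 26.6% lie opposite Gm15469, and the strand setting of the counting is not given in the sources used here.

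**Figure D2:**
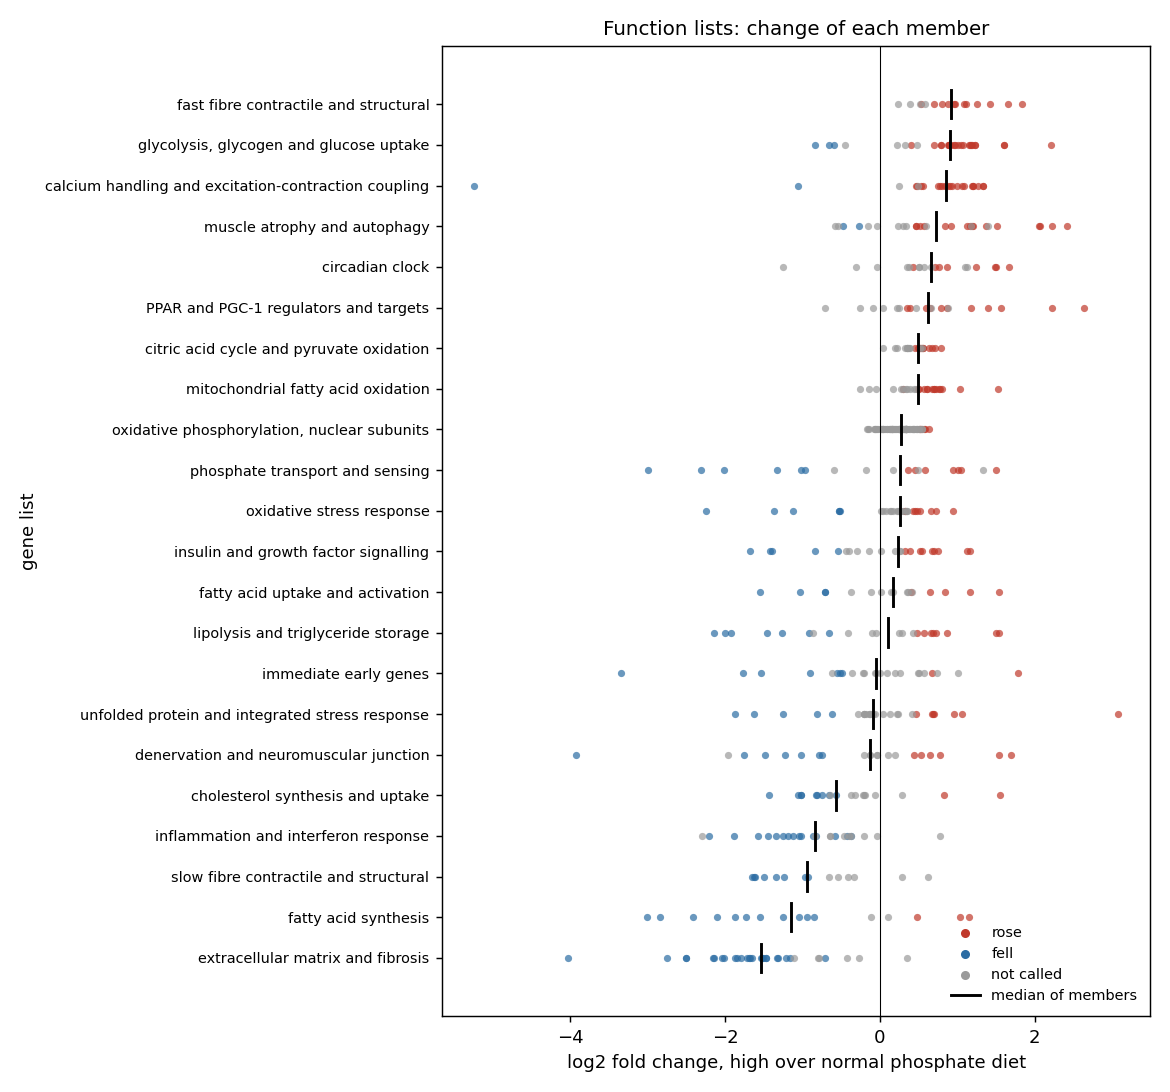
Log2 fold change of each tested member of 22 function lists, high over normal phosphate diet (horizontal axis, TMM-normalized), one list per line; red members rose, blue members fell, grey members were not called, and the black bar is the list's median. The medians run from -1.53 for extracellular matrix and fibrosis to 0.92 for fast fibre genes, and with library size alone the medians of fatty acid uptake, lipolysis, oxidative phosphorylation, phosphate transport, insulin signalling and oxidative stress turn negative.

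Connective tissue and inflammation genes fell. In the list of extracellular matrix and fibrosis, 0 rose and 25 fell of 31 measured, and 26 changed when adjusted over the list alone (median -1.53; camera adjusted p = 2.83e-06, and adjusted p = 0.566 with an estimated correlation). Mmp2, a collagen-degrading protease (350 ± 156 to 85.4 ± 9.73 CPM, -2.03 ± 0.29), its kind of inhibitor Timp1 (-2.51 ± 0.37) and the growth factor Tgfb1 (-1.21 ± 0.17) fell. In the list of inflammation and interferon response, 0 rose and 15 fell of 25, and 16 changed when adjusted over the list alone (median -0.84; camera adjusted p = 0.000485, and adjusted p = 0.566 with an estimated correlation). Examples were the adhesion molecule Vcam1 (-1.19 ± 0.20), the class I histocompatibility gene H2-D1 (-1.13 ± 0.22) and Ifi27 (-0.57 ± 0.11). In the same libraries the fibroblast marker score differed by -0.83 (95% interval -1.30 to -0.37), the macrophage score by -1.36 (95% interval -2.17 to -0.55) and the lymphocyte score by -3.21 (95% interval -4.89 to -1.52) on the log2 scale.

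Cholesterol genes fell weakly: in the list of cholesterol synthesis and uptake, 2 rose and 9 fell of 19, and 12 changed when adjusted over the list alone (median -0.57; camera adjusted p = 0.0467, and adjusted p = 0.730 with an estimated correlation). Srebf2, its main transcription factor (-0.74 ± 0.11), and the enzyme Sqle (-1.44 ± 0.27) fell, while Hsd17b7 rose (1.56 ± 0.21). The list lost its call with library size alone (camera adjusted p = 0.101), on the log2(FPKM + 1) scale (0.0679), without normal phosphate replicate 1 (camera adjusted p = 0.0623) or 3 (0.118), and without high phosphate replicate 1 (0.0643), 2 (0.0654) or 3 (0.118). Circadian clock genes rose, 8 of 19 with 0 falling and 8 changed when adjusted over the list alone (median 0.67; camera adjusted p = 0.00281, and adjusted p = 0.566 with an estimated correlation). Per1 (1.51 ± 0.20), Rora (1.24 ± 0.14) and Hlf (1.49 ± 0.29, but 0.47 and not called on the log2(FPKM + 1) scale) were among them. The scores of white adipocytes (-1.93), macrophages (-1.36) and fibroblasts (-0.83) were lower in the libraries in which these 2 lists differed.

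The remaining function lists were not called by camera, and their members moved both ways. Of insulin and growth factor signalling genes, 9 rose and 5 fell of 22 with 17 changed when adjusted over the list alone (camera adjusted p = 0.283), and fry called the list as higher (fry adjusted p = 0.0116). Its mean was -0.0089, and its median of 0.23 turned to -0.24 with library size alone and to -0.20 on the log2(FPKM + 1) scale. Tbc1d1 (1.12 ± 0.10) rose and Igfbp3 (-1.39 ± 0.20) fell, and Gsk3b rose (0.70 ± 0.10) but turned to -0.11 and was not called on the log2(FPKM + 1) scale, nor was it called with library size alone (0.23). Of oxidative stress genes, 9 rose and 6 fell of 30 with 15 changed when adjusted over the list alone (camera adjusted p = 0.0531), among them Txnrd2 (0.73 ± 0.11; 0.26 and not called with library size alone), Sod3 (-1.12 ± 0.15) and the phagocyte oxidase subunit Cybb (-2.24 ± 0.32). The median of 0.26 turned to -0.20 with library size alone and to -0.18 on the log2(FPKM + 1) scale. This list was called as higher without normal phosphate replicate 1 (camera adjusted p = 0.0150), high phosphate replicate 1 (0.0395) or 3 (0.0351), and with no filter on low counts (0.00670). Of unfolded protein and integrated stress response genes, 7 rose and 5 fell of 27 with 12 changed when adjusted over the list alone (camera adjusted p = 0.687). Chac1, given above among the largest increases of all genes, was one of those that rose, whereas the serine synthesis enzymes Phgdh (-1.87 ± 0.13) and Psat1 (-1.63 ± 0.16) fell. About 47.8% of the 50-base stretches of Phgdh occur in other transcripts, among them Gm7901. Of immediate early genes, 2 rose and 7 fell of 24 with 9 changed when adjusted over the list alone (camera adjusted p = 0.501). Egr3 (-3.34 ± 0.39) and Ier2 (-0.90 ± 0.14) fell and Nr4a1 (1.79 ± 0.32) rose. Of denervation and neuromuscular junction genes, 6 rose and 7 fell of 21 with 14 changed when adjusted over the list alone (camera adjusted p = 0.687). Musk, the receptor kinase of the junction (1.69 ± 0.15), and the perinatal myosin Myh8 (1.54 ± 0.22) rose, and the transcription factor Runx1 (-1.76 ± 0.23) fell. Counts of Myh8 are uncertain, since 12.1% of its 50-base stretches occur in transcripts of other genes, among them Myh2, Myh1 and Myh4. Myh4 had 1373080 counts on the normal and 3281066 on the high phosphate diet, against 24753 and 54079 for Myh8. Whether reads from Myh4 account for the rise of Myh8 was not tested.

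Markers of several cell types other than muscle fibres were lower on the high phosphate diet. White adipocyte markers fell: 0 rose and 13 fell of 14, 14 changed when adjusted over the list alone, and the median was -1.99 (camera adjusted p = 1.2e-06, and adjusted p = 0.565 with an estimated correlation). Plin1, a lipid droplet protein, fell from 134 ± 23.2 to 23.9 ± 5.91 CPM (-2.49 ± 0.19), and Pnpla3 (-2.14 ± 0.14) and Adipoq (-2.19 ± 0.21) fell too. Macrophage and monocyte markers fell, 13 of 15 with 1 rising and 14 changed when adjusted over the list alone (median -1.4; camera adjusted p = 0.000278, and adjusted p = 0.565 with an estimated correlation), among them Cd68 (-2.07 ± 0.22), Ccr2 (-1.71 ± 0.20) and Lyz2 (809 ± 242 to 204 ± 42.3 CPM). Lymphocyte markers fell, 11 of 12 with 1 rising and 12 changed when adjusted over the list alone (median -4.19; camera adjusted p = 0.000278, and adjusted p = 0.565 with an estimated correlation), including Cd4 (-3.98 ± 0.43), Cd8a (-4.93 ± 0.79) and Cd2 (-2.15 ± 0.29). On the log2(FPKM + 1) scale the lymphocyte list was not called (camera adjusted p = 0.0756), and only 1 of its 12 markers was above 1 CPM in every library. Fibroblast and fibro-adipogenic progenitor markers fell, 9 of 12 with 0 rising and 9 changed when adjusted over the list alone (median -0.89; camera adjusted p = 0.00178, and adjusted p = 0.565 with an estimated correlation), including Dpt (-1.33 ± 0.17), Clec3b (-0.98 ± 0.13) and Cd34 (-1.02 ± 0.15).

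Endothelial markers fell by less, 9 of 12 with 0 rising and 11 changed when adjusted over the list alone (median -0.57; camera adjusted p = 0.0127, and adjusted p = 0.589 with an estimated correlation). Cldn5 (-1.59 ± 0.14), Egfl7 (-0.56 ± 0.10) and Tie1 (-0.70 ± 0.14) were its members with the smallest p. Tendon markers fell, 5 of 10 with 0 rising and 5 changed when adjusted over the list alone (median -0.82; camera adjusted p = 0.0394, and adjusted p = 0.618 with an estimated correlation), including Tnmd (-2.19 ± 0.47), Cilp2 (-1.77 ± 0.42, and -1.13 without normal phosphate replicate 2) and Thbs4 (-0.97 ± 0.24). With no filter on low counts Tnmd (-2.17) and Cilp2 (-1.75) were not called. Both lists lost their calls with library size alone (camera adjusted p = 0.0842 and 0.206) and on the log2(FPKM + 1) scale (0.0756 and 0.197), and the tendon list also lost it with the replicate number as a block (camera adjusted p = 0.0567) and without high phosphate replicate 1 (camera adjusted p = 0.0562) or 2 (0.122). The other cell type lists were not called by camera, but fry called the brown adipocyte and the pericyte and smooth muscle lists as lower (fry adjusted p = 0.00225 and 0.0208). For pericyte and smooth muscle genes 1 rose and 4 fell of 10 (camera adjusted p = 0.117), with Cspg4 at -1.03 ± 0.13, Pdgfrb at -1.06 ± 0.14 and Kcnj8 at -0.73 ± 0.10. For brown adipocyte genes 1 rose and 3 fell of 7 (camera adjusted p = 0.117, but 0.0289 with no filter on low counts and 0.0413 with a filter of 1 CPM), with Dio2 at -2.29 ± 0.31, Kcnk3 at -1.64 ± 0.24 and Ebf2 at -0.83 ± 0.26, the last not called without normal phosphate replicate 2 (-0.74) or 3 (-0.82) and at -0.54 without high phosphate replicate 1, and not called with no filter on low counts (-0.82) or on the log2(FPKM + 1) scale (-1.31). For satellite cell genes 1 rose and 4 fell of 9 (camera adjusted p = 0.286), with Cdh15 at 1.19 ± 0.12 and Heyl at -1.31 ± 0.18. For Schwann cell and nerve genes 0 rose and 2 fell of 12 (camera adjusted p = 0.753), with Scn7a at -1.11 ± 0.12 and Pmp22 at -0.41 ± 0.13, the latter not called without normal phosphate replicate 2 (-0.29) or high phosphate replicate 1 (-0.36) or 3 (-0.33). The Schwann cell median of 0.029 turned to -0.45 with library size alone and to -0.30 on the log2(FPKM + 1) scale, to -0.023 without normal phosphate replicate 1 and to -0.17 without high phosphate replicate 2. For erythroid genes 1 rose and 0 fell of 7 (camera adjusted p = 0.680), with Bpgm at 0.71 ± 0.17 (0.24 with library size alone and 0.21 on the log2(FPKM + 1) scale, not called in either). The erythroid median of 0.40 turned to -0.076 with library size alone and to -0.38 on the log2(FPKM + 1) scale, and to -0.85 without high phosphate replicate 2. Of the neutrophil markers 4 were measured, too few for the set test, and 0 rose and 2 fell, with Csf3r at -1.59 ± 0.27 and Retnlg at -2.44 ± 0.41. The counts adjusted over each of these 6 lists alone were 5, 4, 5, 1, 1 and 2 in that order.

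**Figure D3:**
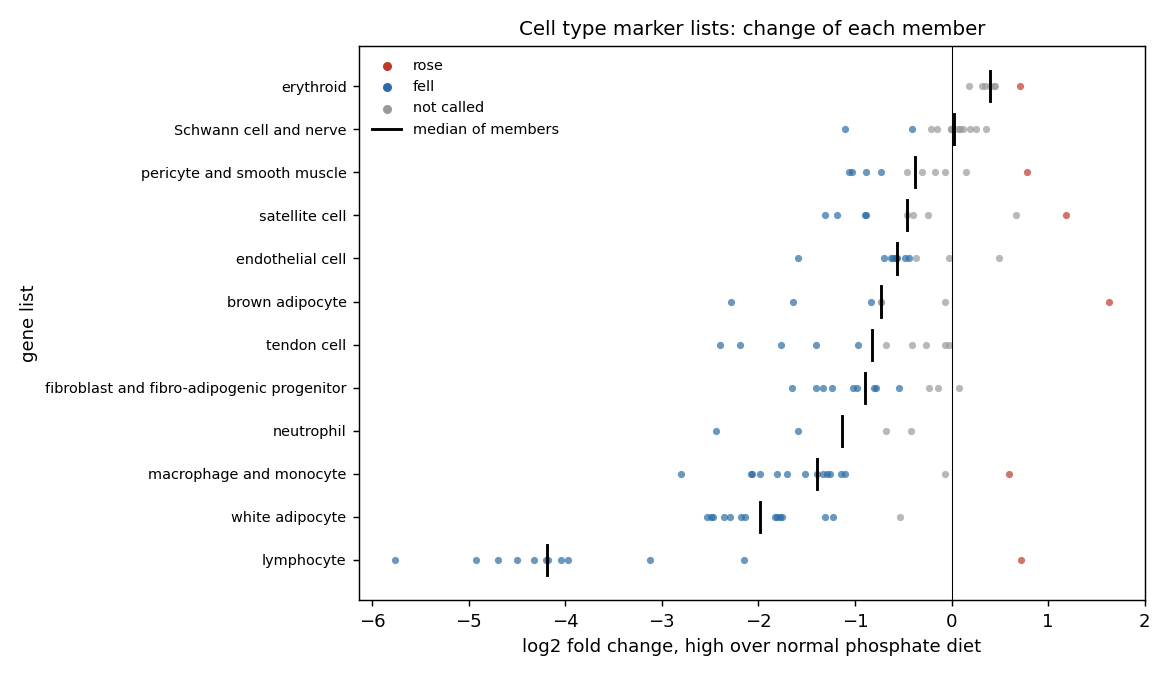
Log2 fold change of each tested marker of 12 cell types, high over normal phosphate diet (horizontal axis, TMM-normalized), one list per line; red markers rose, blue markers fell, grey markers were not called, and the black bar is the list's median. The medians run from -4.19 for lymphocytes to 0.40 for erythroid cells, the latter turning to -0.076 and that of Schwann cells to -0.45 with library size alone.

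Marker scores per library, the mean log2 CPM of a list, were compared by a two-sided exact permutation test, for which 3 against 3 libraries cannot give a p under 0.1. The white adipocyte score differed by -1.93 (95% interval -2.53 to -1.34), high minus normal phosphate, with exact permutation p = 0.10 and an adjusted value of 0.120 over 12 scores. The same p was found for the brown adipocyte (-0.69 (95% interval -0.85 to -0.53)), endothelial (-0.51 (95% interval -0.90 to -0.12)), pericyte (-0.38 (95% interval -0.62 to -0.14)), tendon (-0.93 (95% interval -1.92 to 0.062)), neutrophil (-1.12 (95% interval -1.55 to -0.70)) and satellite cell (-0.38 (95% interval -0.85 to 0.084)) scores, and for the fibroblast, macrophage and lymphocyte scores given above. The erythroid score differed by 0.053 (95% interval -1.85 to 1.95) (exact permutation p = 1), but by -0.42 with library size alone (exact permutation p = 0.600), and the Schwann cell score by -0.084 (95% interval -0.60 to 0.43) (exact permutation p = 0.80), but by -0.55 with library size alone (exact permutation p = 0.20). With library size alone 10 of the 12 scores moved by more than the SD between libraries, all but the erythroid and lymphocyte scores. The differences were then -2.41 for white adipocyte, -1.14 for brown adipocyte, -0.98 for endothelial, -0.85 for pericyte, -1.31 for fibroblast, -1.4 for tendon, -1.83 for macrophage, -3.60 for lymphocyte, -1.55 for neutrophil and -0.85 for satellite cell markers. Hemoglobin genes held 0.0328 ± 0.0140% of the counts on the normal phosphate diet and 0.0285 ± 0.0287% on the high phosphate diet. All camera calls were lost when the correlation between genes was estimated from the data, whereas fry, which asks whether a list's genes move on balance one way, called 12 function lists and 7 cell type lists. Of the lists that camera called, fry did not call those of the citric acid cycle (fry adjusted p = 0.0966), oxidative phosphorylation (0.280), cholesterol (0.160) and tendon (0.122).

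Where 5 or fewer members of a list moved in a direction, those not given above were named after their values had been seen. In fatty acid synthesis the members that rose were Acacb, the carboxylase isoform whose product restrains fatty acid entry into mitochondria (1.16), Me1, a source of NADPH (1.03), and the glucose-sensing transcription factor Mlxipl (0.48). In fatty acid uptake Got2 (0.65) and Acsl6 rose and Cav1 (-0.71) fell. Acsl6 stood at 0.41 but turned to -0.059 with library size alone and to -0.12 on the log2(FPKM + 1) scale. In glucose use Pfkp (-0.83), Hk1 (-0.65) and Pgam1 (-0.59) fell, in calcium handling the pump regulator Pln (-1.06), and in atrophy and autophagy Ctsl (-0.48) and Fbxo21 (-0.27). In insulin and growth factor signalling Igf1 (-1.67), Igf2 (-1.42), Igfbp4 (-0.84) and Pik3r1 (-0.54) fell, and in the unfolded protein and integrated stress response Asns (-1.25), Eif2ak3 (-0.61) and Pdia4 (-0.81). Fdft1 (0.83) of the cholesterol genes and Jun (0.68) of the immediate early genes rose. Among cell type markers Zic1 (1.63) of brown adipocytes, Abcc9 (0.78) of pericytes, Cd163 (0.59) of macrophages and Ighm (0.72) of lymphocytes rose, and Notch3 (-0.89) of pericytes and satellite cells, Pax7 (-0.90) of satellite cells and Comp (-1.4) and Col11a1 (-2.39) of tendon fell. Calls were lost for Acsl6 without normal phosphate replicate 1 (0.42) or 2 (0.27) or high phosphate replicate 1 (0.36) or 3 (0.42), Cd163 without normal phosphate replicate 1 (0.58), 2 (0.73) or 3 (0.47) or high phosphate replicate 1 (0.64) or 2 (0.35) and Col11a1 without normal phosphate replicate 3 (-2.75) or high phosphate replicate 1 (-2.42), 2 (-2.18) or 3 (-2.57). Likewise, calls were lost for Comp without high phosphate replicate 1 (-1.34), Ctsl without high phosphate replicate 1 (-0.49), 2 (-0.51) or 3 (-0.40) and Fbxo21 without normal phosphate replicate 1 (-0.26), 2 (-0.25) or 3 (-0.31) or high phosphate replicate 1 (-0.26), 2 (-0.21) or 3 (-0.31). The same held for Got2 without high phosphate replicate 1 (0.51), Hk1 without high phosphate replicate 3 (-0.62) and Igf2 without high phosphate replicate 1 (-1.29), 2 (-1.45) or 3 (-1.47). It held too for Jun without normal phosphate replicate 2 (0.52) or 3 (0.68) or high phosphate replicate 1 (0.44), Mlxipl without high phosphate replicate 2 (0.47) and Pgam1 without high phosphate replicate 1 (-0.43). Also lost was the call of Zic1 without normal phosphate replicate 1 (1.42) or 2 (1.37) or high phosphate replicate 1 (0.98). Without normal phosphate replicate 2, Col11a1 stood at -1.17, Comp at -0.93 and Igf2 at -0.87. With limma-voom Cd163 (0.56) and Col11a1 (-1.99) lost their calls, as did Cd163 (0.61), Col11a1 (-2.37), Comp (-1.38), Fbxo21 (-0.26) and Igf2 (-1.4) with no filter on low counts, Acsl6 (0.39) and Cd163 (0.57) with a filter of 1 CPM, and Fbxo21 with DESeq2 (-0.24) and with its size factors (-0.26). Library size alone ended those of Cd163 (0.11), Fdft1 (0.36), Got2 (0.17), Jun (0.20), Mlxipl (0.019) and Zic1 (1.14), and the log2(FPKM + 1) scale those of Cd163 (0.089), Col11a1 (-1.0), Fdft1 (0.22), Got2 (0.22), Jun (0.53), Mlxipl (0.34) and Zic1 (0.10). Counts of Igf2, Pln, Pgam1, Me1, Fdft1, Ctsl and Got2 are uncertain, since 62.1%, 56.2%, 36.2%, 28.3%, 26.5%, 26.3% and 25.6% of their 50-base stretches occur in transcripts of other genes.

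Positions are those of GENCODE release M21 on GRCm38, and intervals span the whole gene. Fasn lies on chromosome 11, 120805846 to 120824547, minus strand, 42 merged exons. Acaca lies on chromosome 11, 84129672 to 84401651, plus strand, 59 merged exons, and Adipoq on chromosome 16, 23146536 to 23158028, plus strand, 4 merged exons. Sln lies on chromosome 9, 53850164 to 53854560, plus strand, 2 merged exons. Myh4 lies on chromosome 11, 67238029 to 67260446, plus strand, 39 merged exons, and Myh7 on chromosome 14, 54970684 to 54994626, minus strand, 38 merged exons. Pdk4 lies on chromosome 6, 5483351 to 5496309, minus strand, 11 merged exons, and Fbxo32 on chromosome 15, 58175879 to 58214932, minus strand, 9 merged exons. Xpr1 lies on chromosome 1, 155275701 to 155417415, minus strand, 16 merged exons, Slc20a1 on chromosome 2, 129198764 to 129211616, plus strand, 11 merged exons and Slc20a2 on chromosome 8, 22476788 to 22569612, plus strand, 12 merged exons. Cpt1b lies on chromosome 15, 89416405 to 89425863, minus strand, 19 merged exons.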

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

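Chosen only after the data were seen was the run without cell type markers and immunoglobulin genes, which gave 7508 changed genes. The count of changed genes stayed between 5521 (log2(FPKM + 1), all genes above 0) and 8764 (library size alone) in the runs at the same thresholds, the covariate run aside. Other thresholds gave 2762 at 2-fold or more (686 higher and 2076 lower) and 8972 at an adjusted p under 0.1. Without single libraries it ran from 6152 (without high phosphate replicate 1) to 7577 (without normal phosphate replicate 1). Same-numbered libraries deviated from their diet means with correlations of -0.021, 0.022 and 0.019, so the numbers did not pair them, and the replicate block gave 7328 genes and ended the calls of the tendon list and of Slc20a2 (0.36), Col11a1 (-1.95), Fbxo21 (-0.27) and Zic1 (1.57), at edgeR adjusted p values of 0.0613, 0.0875, 0.0845 and 0.0505. The direction of calls depended on the scaling, with 878 higher and 7886 lower for library size alone, 718 higher on the log2(FPKM + 1) scale, 742 with a pseudocount of 0.1 and 566 over all genes above 0. The cause of these differences was not tested. Depth limits the values of low genes, with a counting error of 21.4% at 1 CPM in the smallest library, and with no filter on low counts 28193 genes were tested and 7799 called. Without single libraries 13 to 14 function lists and 5 to 6 cell type lists were called. Of the gene values, 163 of 164 kept direction and call with DESeq2-style size factors, 162 of 163 with DESeq2, 158 with limma-voom, 151 with no filter on low counts, 160 with the replicate block, 157 of 159 with a filter of 1 CPM, 138 with library size alone and 129 on the log2(FPKM + 1) scale.

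With the white adipocyte score as a covariate, 3 genes were called (1 higher and 2 lower), 4 function lists and 1 cell type list. Diet accounted for 95.3% of the variance of the score, so this run can hardly tell the diet from the score. Some fold changes also shrank or turned, and what share of the lost calls came from either was not tested. The median relative to all genes then lay at -1.11 for fatty acid synthesis and turned for mitochondrial fatty acid oxidation (-0.036), cholesterol synthesis and uptake (0.0058), oxidative phosphorylation, nuclear subunits (-0.16), citric acid cycle and pyruvate oxidation (-0.39), white adipocyte (0.20), endothelial cell (0.33), pericyte and smooth muscle (0.32) and satellite cell (0.11). Log2 fold changes turned for Pax5 (1.12), Ms4a1 (1.55), Cr2 (0.29), Ebf2 (1.99), Pdhx (-0.17), Tie1 (0.27), Lipe (0.47), Adipoq (0.030), Fabp4 (0.22), Slc20a1 (-0.13), Cd36 (0.63), Got2 (-0.64), Hk1 (0.27), Ighm (-0.66), Jun (-1.17), Notch3 (0.092), Pgam1 (0.39), Pik3r1 (0.21) and Zic1 (-1.31). The score is the mean of the white adipocyte list, with Adipoq and Fabp4 among its members. The loss of the change in that list and in these 2 genes is therefore built into the run and is no result.

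Camera with an estimated correlation called 0 function lists and 0 cell type lists at unchanged medians, mitochondrial fatty acid oxidation (0.51) and fatty acid synthesis (-1.13) among the fatty acid lists. On the log2(FPKM + 1) scale 3 cell type lists were called, those of white adipocyte, fibroblast and fibro-adipogenic progenitor and macrophage and monocyte, while the endothelial, tendon and lymphocyte lists were not. Log2 fold changes and list medians relative to all genes turned for Slc20a1 (-0.023), Slc20a2 (-0.11), Cpt1b (-0.075), Pnpla2 (-0.17) and Acsl6 (-0.059) with library size alone. They turned for lipolysis and triglyceride storage (-0.013), erythroid (-0.094), Schwann cell and nerve (-0.014), Gsk3b (-0.11), Slc20a2 (-0.32), Pnpla2 (-0.20) and Acsl6 (-0.12) on the log2(FPKM + 1) scale. They turned for Gsk3b (-0.12), Slc20a2 (-0.35), Pnpla2 (-0.20) and Acsl6 (-0.14) with a pseudocount of 0.1. They turned for Gsk3b (-0.11), Slc20a2 (-0.32), Pnpla2 (-0.20) and Acsl6 (-0.12) over all genes above 0 in FPKM. They turned for unfolded protein and integrated stress response (0.11), immediate early genes (0.15) and denervation and neuromuscular junction (0.081) with no filter on low counts. They turned for erythroid (-0.0098) with the replicate block. Without single libraries the log2 fold change ran from -0.31 to 0.028 for Cd36. List medians, here relative to the median of all genes, ran from -0.13 to 0.24 for Schwann cell and nerve, -0.13 to 0.050 for denervation and neuromuscular junction, -0.81 to 0.80 for erythroid, -0.0077 to 0.34 for fatty acid uptake and activation, -0.083 to 0.088 for immediate early genes, -0.0033 to 0.19 for lipolysis and triglyceride storage and -0.093 to 0.078 for unfolded protein and integrated stress response. The cause of these turns was not tested.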

Other observations

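Chosen only after the data had been seen were the added gene lists of this part, the genes named from them, and the tests of less adipocyte RNA, brown fat (with its genes), fibre share (both), blood, time of day, a fasted state and the cell cycle genes. Proteasome subunit genes rose relative to other genes on the high phosphate diet: 17 rose and 2 fell of 37, with 19 changed when adjusted over the list alone (median 0.24, and -0.23 with library size alone, where 14 of those that rose were not called; camera adjusted p = 3.36e-05, and adjusted p = 0.612 with an estimated correlation). Their mean relative to all genes differed by 0.40 (95% interval 0.22 to 0.59), high minus normal phosphate, a change in the direction of the atrophy genes. In this part a mean relative to all genes is taken against the mean log2 CPM of all genes tested, not against their median. Psmd8 (0.98 ± 0.14) and Psmd7 (0.81 ± 0.12), parts of the regulatory particle, rose, while the immunoproteasome subunits Psmb8 (-1.25 ± 0.34) and Psmb10 (-0.43 ± 0.12) fell. Psmb8 lost its call without normal phosphate replicate 2 (-1.13) or high phosphate replicate 2 (-1.08), and Psmb10 without high phosphate replicate 2 (-0.38) or 3 (-0.36). Mitochondrial ribosomal protein genes moved with the oxidation genes: 29 rose and 0 fell of 73, with 28 changed when adjusted over the list alone (median 0.32, and -0.14 with library size alone, where 29 of those that rose were not called; camera adjusted p = 5.56e-07, and adjusted p = 0.612 with an estimated correlation), at a mean relative to all genes of 0.47 (95% interval 0.077 to 0.87). Mrpl16 (0.56 ± 0.12; 0.094 and not called with library size alone) was the member with the smallest p. In fry the unadjusted p was 0.0621 for the mitochondrial ribosomal list and 0.0036 for the proteasome list. In both lists the mean relative to all genes lay above the median. How much of these means comes from the reference used was not tested. In the libraries in which proteasome and mitochondrial ribosomal genes were higher, the white adipocyte (-1.93), macrophage (-1.36) and fibroblast (-0.83) scores were lower.

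Of cytosolic ribosomal protein genes, 2 rose and 4 fell of 83, with 2 changed when adjusted over the list alone (median -0.064, and -0.53 with library size alone; camera adjusted p = 0.434, and adjusted p = 0.892 with an estimated correlation). Their mean relative to all genes was 0.081 (95% interval -0.19 to 0.35), of the opposite sign to the median, which is not taken against the mean of all genes. Neither a change nor its absence could be settled. The list was called as lower without normal phosphate replicate 2 (median -0.12, camera adjusted p = 0.0290), and the median was 0.0024 without normal phosphate replicate 1. Within the list Rpl3 (-1.07 ± 0.16) and Rpl39 (-0.58 ± 0.12) fell, as did Rps27a (-0.38 ± 0.13) and Rps4l (-0.63 ± 0.21), the last typed in release M21 as a transcribed processed pseudogene. Rpl3l, the muscle paralog of Rpl3, rose (0.62 ± 0.22), as did Rps20 (0.39 ± 0.14), which turned to -0.077 with library size alone. Rpl3l lost its call without normal phosphate replicate 3 (0.70) or high phosphate replicate 1 (0.60), 2 (0.62) or 3 (0.69), and with library size alone (0.17). Rps20 lost its call without normal phosphate replicate 1 (0.44), 2 (0.31) or 3 (0.42) or high phosphate replicate 1 (0.44), 2 (0.40) or 3 (0.37). Rps4l lost its call without normal phosphate replicate 1 (-0.62), 2 (-0.61) or 3 (-0.66) or high phosphate replicate 1 (-0.52) or 2 (-0.47), and Rps27a without normal phosphate replicate 1 (-0.34) or 3 (-0.36) or high phosphate replicate 1 (-0.36), 2 (-0.35) or 3 (-0.39). Other genes' transcripts, pseudogene transcripts among them, hold 35% of the 50-base stretches of Rpl3 and 26.3% of those of Rps27a, so the counts of these genes are uncertain. Of cell cycle genes, 2 rose and 10 fell of 21, with 13 changed when adjusted over the list alone (median -1.15, and -1.68 with library size alone; camera adjusted p = 0.0172, and adjusted p = 0.612 with an estimated correlation). Rrm2 (-1.47 ± 0.25) and Plk1 (-1.85 ± 0.46) fell, while the spindle genes Aurka (2.03 ± 0.21) and Tpx2 (1.6 ± 0.28) rose. Birc5, Ccnb2, Cdk1, Kif23, Mki67, Prc1 and Top2a fell too, but each lost its call without high phosphate replicate 2 and without high phosphate replicate 3. In fry the cell cycle list had an unadjusted p of 0.107. The list lost its call without high phosphate replicate 2 (median -1.06, camera adjusted p = 0.0550), and the median was -0.60 without normal phosphate replicate 2. The mean of the list relative to all genes was -0.71 (95% interval -1.79 to 0.36), an interval that includes 0. Of imprinted growth genes, 0 rose and 6 fell of 12, with 8 changed when adjusted over the list alone (median -1.68, and -2.21 with library size alone; camera adjusted p = 0.00521, and adjusted p = 0.612 with an estimated correlation), led by Peg3 (-1.97 ± 0.23) and Plagl1 (-2.16 ± 0.33), although the median was -0.84 without normal phosphate replicate 2. The macrophage (-1.36), lymphocyte (-3.21) and fibroblast (-0.83) scores were lower in the libraries in which cell cycle and imprinted genes were lower.

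Among the 10 ways to split the 6 libraries into 3 and 3, only the diet split (1 of 10) gave as many called genes in edgeR, 7563 against at most 0 in the others. At an unadjusted p under 0.05 the others gave 57 to 224 genes. So few splits cannot give a share under 0.05. The other splits also mix the diets within their groups, so the difference between diets widens the spread there. Their calls are therefore no measure of what chance alone would give.

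White adipocyte markers and fatty acid synthesis genes were lower together on the high phosphate diet. Brown fat in the normal phosphate muscles is argued against as the source, since Ucp1, Cidea and Elovl3, abundant in that tissue, together had 0.549% of the counts of Adipoq there (95% counting interval 0.441 to 0.674), with 1 count of Ucp1 in all, under a limit of 1% that was set after these counts were seen, whereas the brown adipocyte list, with 3 of 7 genes above 1 CPM in every library, was too low to decide. Less adipocyte RNA in the high phosphate libraries is a candidate explanation, with an adipocyte score (of 14 genes, 0 of them in other lists and 14 above 1 CPM in every library, with Fabp4 among the most abundant at 1034 ± 50.04 and 440 ± 98.6 CPM) that differed by -1.93 and a synthesis list whose mean change lay 0.89 (95% interval 0.26 to 1.53) above it. Among the named synthesis genes Fasn (-3.01 ± 0.25), Slc25a1 and Elovl6 nevertheless fell further than the score. The list mean also includes Acacb (1.16), Me1 (1.03) and Mlxipl (0.48), which rose. It therefore does not show that the lower members followed the score. With the score as a covariate the synthesis median went from -1.15 (SD over members 1.30) to -1.09 (1.37) and Fasn to -3.20 ± 1.15, a like change with a larger error. The calls of the synthesis genes ended in this run, in which diet accounted for 95.3% of the variance of the score. An effect of the diet on synthesis genes within the fibres stays open and was not tested.

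Markers of several cell types other than fibres were lower on the high phosphate diet. An even rise in the share of fibre RNA is argued against as the whole cause, since the Schwann cell list stood above the macrophage list by 1.28 (95% interval 0.52 to 2.03) in the change between diets. This pair was picked after the scores were seen, from among the least (-0.084) and the most (-1.36) lowered. The interval does not allow for that choice. More blood in the normal phosphate muscles is argued against for the lymphocyte genes, since the erythroid list stood above the lymphocyte list by 3.26 (95% interval 1.32 to 5.2). That argument is limited, as only 1 of 12 lymphocyte genes was above 1 CPM in every library. The erythroid score itself differed by 0.053 with a wide 95% interval (-1.85 to 1.95). Normal phosphate replicate 2, which lay apart on the first principal component, was not the only source, as 6 of 6 called cell type lists were still called without it. A difference in immune, fat and connective tissue cells brought about by the diet, or by how much neighbouring tissue was taken with the muscle, stays open and was not tested.

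Atrophy genes, Pdk4 and Ucp3 were higher while fatty acid synthesis genes were lower on the high phosphate diet, and more fibre RNA with all fibre genes raised alike is argued against as the whole cause of the higher genes, since these stood above slow fibre genes by 1.70 (95% interval 1.18 to 2.23), the latter being lower (a mean of -0.85). Both directions were known when this comparison was chosen, and a change in fibre type is not covered by it. A different time of day at collection cannot be told apart from the diet, since clock genes of opposite phase differed by 0.73 (95% interval -1.54 to 3.01), with 0.82 for the arm of Dbp and the Per genes and 0.087 for the arm of Arntl, an interval too wide to decide. A more fasted state of the high phosphate mice may also account for it. A list of 20 genes known to rise in fasted muscle has 16 also in the fixed lists. It holds Foxo1, Foxo3 and Klf15 of the atrophy list, so it is not independent of the atrophy genes. The mean of the fasting list relative to all genes was 0.53 (95% interval -0.13 to 1.2), which includes 0. Of that list 9 rose and 2 fell of 20, with 11 changed when adjusted over the list alone (median 0.54, and 0.057 with library size alone, where 4 of those that rose were not called; camera adjusted p = 0.0805, and adjusted p = 0.612 with an estimated correlation), and the list was called without normal phosphate replicate 2 (camera adjusted p = 0.0305) or high phosphate replicate 1 (0.0450) or 3 (0.0123) and had a median of 0.18 without high phosphate replicate 2, the lower members being Pik3r1 (-0.54 ± 0.13) and Ppp1r3b (-1.03 ± 0.32, not called without normal phosphate replicate 2 (-0.99) or 3 (-0.91) or high phosphate replicate 1 (-1.01) or 3 (-0.76)). The diet itself and a loss of other cells together with a change in fibre type, with the white adipocyte (-1.93), macrophage (-1.36) and fibroblast (-0.83) scores lower and fast fibre genes higher (a median of 0.92) in the same libraries, stay open and were not tested, and neither feeding state nor collection time is given in the sources used here.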
